A study of Homo sapiens with 6 samples.

How the data were processed

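HEPM, a cell line of human embryonic palatal mesenchyme, was profiled by RNA sequencing after transfection with an siRNA against ARHGAP29 or with a non-targeting siRNA, with 3 libraries per group. Per the labels' protocols, ribosomal RNA was removed from total RNA and strand-specific paired-end libraries were made. The series' design text calls the libraries of a group independent biological replicates. The time after transfection and the siRNA sequences are not given in the sources used here.

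Per the submitters' processing notes, FastQC 0.11.8, fastp 0.19.5, STAR 2.7.10b, StringTie 1.3.5 and DESeq2 1.10.1 were used, with genome build GRCh38 (hg38). The notes as used here do not give the order of these steps, the annotation version or the strand setting of the counting. The deposited values are whole-number read counts per gene, not normalized, and FPKM per gene computed by the authors, in 2 tables over the same 19655 genes and 6 libraries. FPKM was 0 in exactly the cells where the count was 0. Over 10059 genes with more than 100 counts in every library, the ratio of count to FPKM differed between libraries by a nearly constant factor (median SD 0.00117 on the log2 scale after centring). The FPKM table therefore adds little to the counts and served as an alternative. Of the gene names, 19560 are in the reference table of symbols, and 349 names are Ensembl identifiers. Coordinates are those of the deposited table, on GRCh38. Genes outside this table were not analysed here.

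Totals were between 26966776 and 47150470 counts per library. Genes with enough counts by edgeR's filterByExpr were kept, which left 13815 genes holding 99.98% of all counts, and 3836 genes had no count in any library. Libraries were scaled by TMM, and CPM values use the TMM-scaled library sizes. The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, robust) of ARHGAP29 siRNA against control siRNA with group as the only term. Benjamini-Hochberg adjustment was applied over all genes tested, with a threshold of 0.05. Fold changes are fitted log2 values, siRNA over control, with a standard error taken from the fold change and the F statistic, and with 95% intervals. The target was also compared by an exact two-sided permutation test of CPM, whose smallest possible p with 3 against 3 libraries is 0.1. Log2 CPM used a prior count of 2.

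A set of 35 gene lists, covering pathways, processes and markers of other cell types, was fixed before the data were examined. Of these, 34 had 5 or more tested members and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The list of RNA-quality genes had 1 of its 17 members in the table and was not tested. For each list the number of members past the gene test was counted over all genes and adjusted over the list alone.

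Named genes followed a rule fixed before the data were examined. It takes ARHGAP29, the genes past the edgeR threshold with the largest change or smallest p and a mean log2 CPM of 1 or more whose groups do not overlap, up to 4 members with the smallest p from each list, and the relatives ARHGAP45 and GMIP. Because edgeR called 1 gene, a second rule was added after values were seen. It takes the 12 higher and 12 lower genes with the smallest DESeq2 adjusted p among those with a mean log2 CPM of 1 or more whose groups do not overlap. ATF7-NPFF, NPFF, CANT1, CENPH, TMEM184B, HLA-G and ENSG00000284057 were also chosen after their values were seen.

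The test was checked on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed by known folds and the set described next raised. In that simulation of the siRNA comparison, edgeR recovered 10.4%, 32.8% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold over 13574 genes, and 9 of its 99 calls were false. DESeq2 (1.42.0) recovered 14.9%, 55.2% and 97.0% over 13815 genes, and 48 of its 160 calls were false. Camera gave p = 2.30e-17 for a simulated set of 35 genes raised by 0.5 on the log2 scale, and p = 0.000935 with an estimated correlation, while 1 and 0 of 100 unchanged sets fell under 0.05. The shares recovered and false depend on the number of genes changed in the simulation. EdgeR made 99 calls there and 1 in the data, so these shares need not hold for the data. Simulated genes were drawn independently, so this check does not cover lists whose members vary together. The lists past camera in the data had estimated correlations of 0.0562 to 0.257.

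Alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), no low-count filter and a stricter one (CPM of 1 or more in at least 3 libraries). Others were the DESeq2 Wald test with independent filtering at 0.1 and limma-voom. Limma-trend was run on log2(FPKM + 1) and log2(FPKM + 0.1) with a filter of FPKM of 1 or more in 3 libraries. On log2(FPKM + 1) it was also run without that filter. The remaining alternatives were the replicate number as a block, leaving out each library, and an adjusted p of 0.01. Added after the data were seen were edgeR without robust estimation and DESeq2 with each library left out, with the block and with TMM-based size factors. Counts of libraries of a group were compared for deposits of the same library, and chi-square per degree of freedom over genes was between 47.5 and 164.7 in the 6 pairs, so no pair agreed within sampling noise. No column of per-sample values was left out. Figures were drawn with matplotlib 3.10.9 and R was version 4.3.3.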

Results

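Transcript levels were measured in HEPM cells, a mesenchymal line from the human embryonic palate, 3 libraries after ARHGAP29 siRNA and 3 after a non-targeting control siRNA. ARHGAP29 is a GTPase-activating protein for RhoA that acts downstream of Rap1, and variants in the gene have been linked to cleft lip and palate. The comparison asks what the palatal cells' transcriptome looks like when ARHGAP29 is depleted. Control libraries 1, 2 and 3 held 41504980, 26966776 and 45982435 counts, and ARHGAP29 siRNA libraries 1, 2 and 3 held 41483822, 33537581 and 47150470. Between 14086 and 14715 genes had at least 1 count per library.

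The type I collagen genes COL1A1 and COL1A2 together took 13.4%, 16.6% and 9.96% of the counts in control libraries 1, 2 and 3, and 10.9%, 10.3% and 7.57% in the siRNA libraries. Control library 2, the shallowest, stood apart from the other libraries. On the first principal component of log2 CPM, which held 35.8% of the variance, its score was 77.5, against scores from -26.0 to -1.67 in the other 5. Its mean Pearson correlation with the other libraries across genes was 0.946, against 0.960 to 0.964 for the others. Libraries of different groups correlated at 0.959 on average, between the means within control (0.954) and within ARHGAP29 siRNA (0.967).

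ARHGAP29 itself (chromosome 1, 94168905 to 94237633) was lower in all 3 libraries that received its siRNA. It had 28.2 ± 2.45 CPM in control (SD, n = 3) and 12.3 ± 0.844 CPM after siRNA (SD, n = 3), so 43.6% of the control level remained (95% interval 34.7% to 54.9%). Raw counts were 1066, 802 and 1234 in the control libraries and 472, 453 and 617 in the siRNA libraries. The deposited FPKM were 2.22 ± 0.140 and 1.03 ± 0.0837 (SD, n = 3). The relatives ARHGAP45, at 87.5% of control (95% interval 68.9% to 111.3%), and GMIP, at 103.8% (86.6% to 124.4%), had edgeR adjusted p = 0.923 and 0.967. For ARHGAP29 the log2 fold change of -1.20 ± 0.14 (SE) had an unadjusted p of 5.43e-05 and an adjusted p of 0.15 in edgeR's quasi-likelihood test over 13815 genes, which is not past 0.05. DESeq2 called it with an adjusted p of 6.15e-11, and the exact two-sided permutation test of CPM gave p = 0.1, the smallest it can give.

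EXTL3, which encodes a glycosyltransferase of heparan sulfate chain synthesis, rose 7.43-fold and was the gene past the threshold in edgeR (chromosome 8, 28622732 to 28756561). Its level went from 16.4 ± 3.08 to 122.0 ± 19.4 CPM (SD, n = 3 per group), a log2 fold change of 2.89 ± 0.20 (SE) with an edgeR adjusted p of 0.0173. EXTL3 was higher in each siRNA library than in each control library. No gene passed as lower in edgeR, where 786 genes had an unadjusted p under 0.05 (391 higher and 395 lower) against 690.75 by chance. DESeq2 called 74 genes, 38 higher and 36 lower, and 32 of them by at least 2-fold (14 higher and 18 lower), and limma-voom called 1. The DESeq2 count was 56 to 204 with 1 library left out (204 without control library 2) and 142 with a replicate block. Leaving out control library 1 or 3, or siRNA library 1 or 3, ended the EXTL3 call (edgeR adjusted p = 0.0902, 0.0783, 0.151 and 0.0586; range over all alternatives 1.13e-38 to 0.151), while its log2 fold change stayed between 2.75 and 3.02. Of the 1751 genes whose groups did not overlap in CPM (12.7% of those tested, against 10% by chance), 938 were higher and 813 lower.

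**Figure D1:**
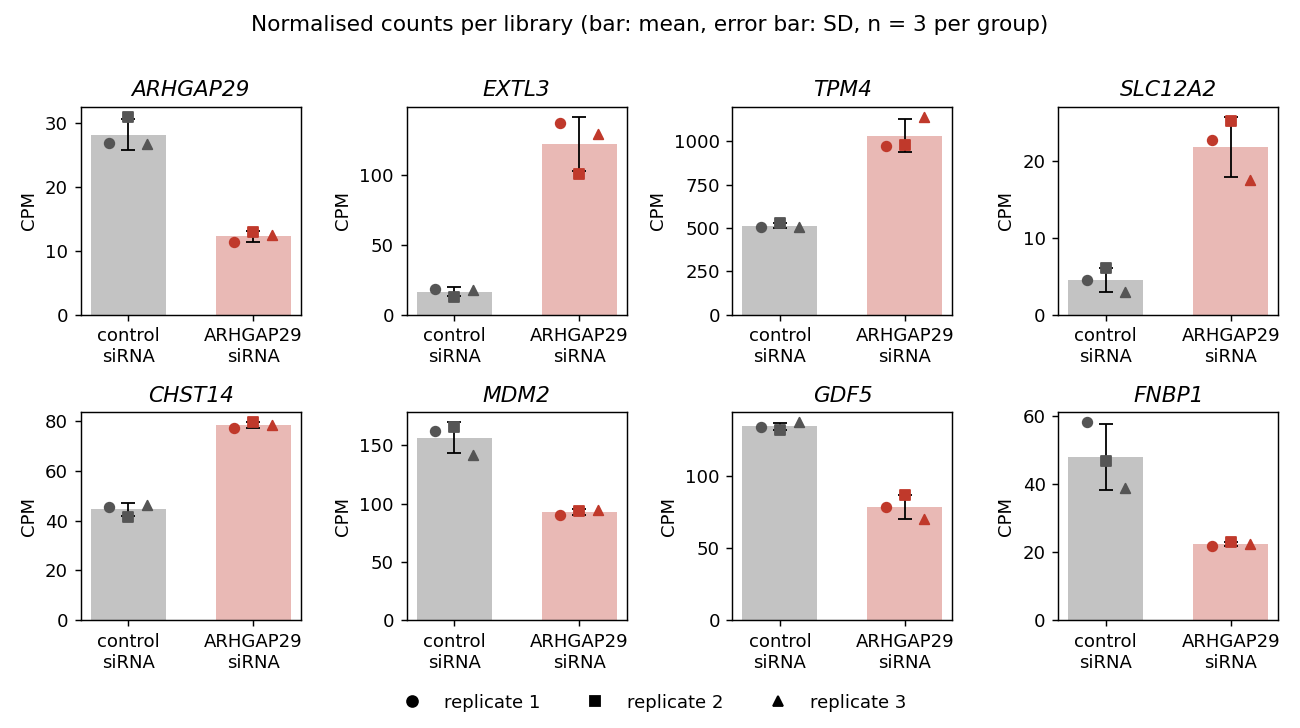
CPM of 8 genes in each library (vertical axes, from 0) by siRNA group, with bars for the mean, error bars for the SD (n = 3) and a marker shape per replicate number. ARHGAP29 was at 12.3 CPM after its siRNA against 28.2 in control, and EXTL3 at 122.0 against 16.4.

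Among the DESeq2 calls, chosen after values were seen, TPM4, a tropomyosin of actin filaments, had 513 ± 14.5 CPM in control and 1031 ± 95.7 after ARHGAP29 siRNA (SD, n = 3), 2.01-fold higher (edgeR adjusted p = 0.0847, DESeq2 adjusted p = 1.56e-13). SLC12A2, the sodium-potassium-chloride cotransporter NKCC1, was 4.89-fold higher (4.50 ± 1.59 against 21.9 ± 3.93 CPM). CHST14, which sulfates dermatan sulfate, was 1.76-fold higher (44.5 ± 2.64 against 78.4 ± 1.07 CPM). PCNX3 was 1.66-fold, RGS19 1.87-fold, CMTM4 2.40-fold, NDUFB10 2.26-fold and ADRA1D 3.17-fold higher, and the dynein adaptor gene BICD2, KLHDC3 and GPRIN1 were 1.65-fold, 1.49-fold and 1.46-fold higher. The DESeq2 adjusted p of these genes ranged up to 0.000445, and apart from TPM4 their edgeR adjusted p lay between 0.134 and 0.347.

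On the lower side, MDM2, the ubiquitin ligase that degrades p53, had 157 ± 13.2 CPM in control and 92.9 ± 2.30 after siRNA (SD, n = 3; DESeq2 adjusted p = 9.74e-07, edgeR adjusted p = 0.184). GDF5, a growth factor of the BMP family that acts in joint formation, had 133.9 ± 2.72 and 78.3 ± 8.41 CPM. FNBP1, which encodes a membrane-bending protein linked to actin assembly, had 47.9 ± 9.67 and 22.3 ± 0.62 CPM. COA8 was at 0.145 of its control level, RMND5A at 0.413, the lysosomal membrane gene SCARB2 at 0.554, HIPK3 at 0.597 and CEND1 at 0.620. The bradykinin receptor gene BDKRB2 was at 0.656, SDSL at 0.687 and PLEKHG4 at 0.748 of control. Apart from MDM2, the lower genes named here had edgeR adjusted p between 0.249 and 0.660 and DESeq2 adjusted p up to 0.0125. COA8 varied within control, with 618, 510 and 250 counts against 66, 54 and 133 after siRNA. With each of the 6 libraries left out in turn, DESeq2 called BDKRB2 and CEND1 in 3 fits, SDSL in 2 and PLEKHG4 in 1, KLHDC3 and GPRIN1 in 5, and TPM4, MDM2 and the others of the higher and lower genes above in all 6. In the simulation of this comparison 48 of DESeq2's 160 calls were false, against 9 of edgeR's 99. All 72 DESeq2 calls that edgeR tested had the same direction there and an unadjusted edgeR p under 0.05. Both tools used the same counts, so this is no independent support. The 2 further calls, HLA-G and ENSG00000284057, were not tested in edgeR. HLA-G had 2, 112 and 201 counts in control and 3 in each siRNA library. ENSG00000284057 had 0, 75 and 0 in control and 0 in each siRNA library.

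Several DESeq2 calls rest on genes whose counts jump between libraries or overlap another gene. ATF7-NPFF, a readthrough gene (chromosome 12, 53506691 to 53625979), had 102, 78 and 110 counts in control and 0 in each siRNA library, while NPFF, which it overlaps (53506688 to 53507484), had 0, 12 and 0 counts in control and 64, 81 and 59 after siRNA. ATF7, which overlaps ATF7-NPFF over most of its length (53507856 to 53626410), had 14.4, 11.2 and 18.1 CPM in control and 19.3, 18.7 and 19.4 after siRNA. Overlapping genes can share reads, so these values are uncertain. CENPH had 775, 844 and 108 counts in control against 139, 97 and 82, and TMEM184B had 3396, 1745 and 3765 against 15228, 3006 and 18067, and DESeq2 called each in 1 of the 6 fits with a library left out. Of the 74 DESeq2 calls, 19 overlap another listed gene (25.7%), against 29.2% of the tested genes.

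Cell cycle genes were higher as groups after ARHGAP29 siRNA. Of 35 genes of the G1/S transition and DNA replication, 29 had a higher fitted value (median log2 fold change 0.17, camera adjusted p = 5.57e-05), and 14 were higher in every siRNA library than in every control library, with 0 lower. With an estimated correlation the camera adjusted p was 0.547. CDT1, a replication licensing factor, had 86.2 ± 6.42 CPM in control and 110.5 ± 5.11 after siRNA, the helicase genes MCM3 and MCM6 had log2 fold changes of 0.31 ± 0.10 and 0.41 ± 0.13 (SE), and POLA1 of 0.62 ± 0.19. Of 36 G2/M and mitosis genes 28 were higher in value (median 0.13, camera adjusted p = 0.00154, and adjusted p = 0.547 with an estimated correlation), among them BIRC5 (257.4 ± 16.03 against 319.3 ± 16.5 CPM), MKI67, CDK1 and CCNB2. The 41 replication-dependent histone genes, whose near-identical copies can share reads, did not pass (camera adjusted p = 0.0876), with 32 higher and 9 lower. No member of the 3 lists passed over all genes or adjusted over the list alone. Per-library means of the G1/S list overlapped, at -0.0503 in siRNA library 1 against -0.0355 and 0.00135 in control libraries 2 and 3. Those of the G2/M list overlapped too, at -0.0217 in siRNA library 1 against 0.0519 in control library 3. Without control library 3 the medians were 0.27 for G1/S and 0.22 for G2/M, and on FPKM they were 0.27 and 0.21, the latter also with scaling by library size only. The median of all genes also rose there, from -0.02 to 0.07 on FPKM and 0.06 with library size only. Without siRNA library 2 the G2/M call ended (camera adjusted p = 0.0876), although the median there was 0.14. The histone list passed without control library 1 or 3 (0.0484 and 0.00306), with a replicate block (0.0448), with scaling by library size only (0.0374) and on FPKM (0.0300).

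**Figure D2:**
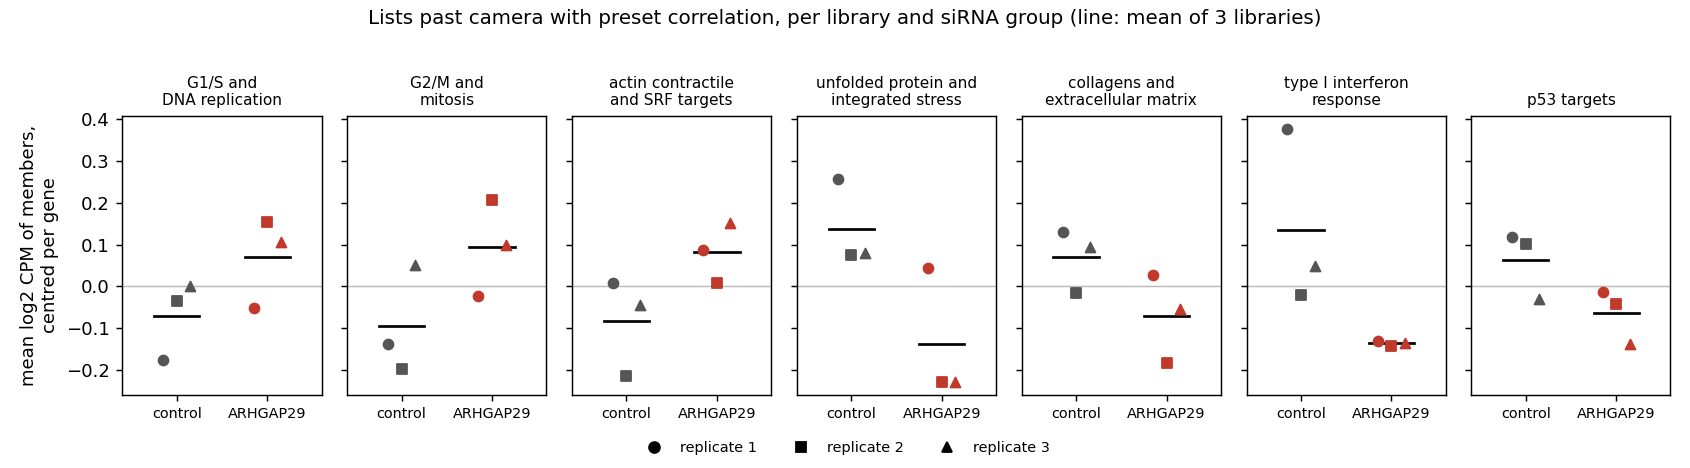
Mean log2 CPM of each list's members, centred per gene (vertical axis), in each library by siRNA group for the 7 lists past camera with the preset correlation, with a line at the mean of 3 libraries. The G1/S mean of ARHGAP29 siRNA library 1 (-0.0503) lies within the control libraries' range, as do its G2/M (-0.0217), matrix (0.0266) and p53 (-0.0127) means. Control library 1 has the highest interferon mean (0.377).

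Actin and SRF target genes were also higher as a group, with 21 of 29 higher in value (median 0.10, camera adjusted p = 0.00504, and adjusted p = 0.654 with an estimated correlation). TPM4 passed when adjusted over the list alone, LPP had a log2 fold change of 0.37 ± 0.11 (SE), CNN1, a smooth muscle calponin, of 0.60 ± 0.20, and CSRP1 of 0.30 ± 0.11. In the list of the RhoA pathway and related GAP genes 15 of 30 were higher and 15 lower in value (camera adjusted p = 0.871). Adjusted over the list alone, DIAPH1, a formin activated by RhoA, passed as higher (93.9 ± 1.28 against 122.2 ± 3.09 CPM), and ARHGEF2, a RhoA exchange factor, passed as lower (252.7 ± 31.3 against 174.7 ± 7.74 CPM). DESeq2 called DIAPH1 (adjusted p = 0.0249) and ARHGEF2 (0.0401), but in 1 and 2 of the 6 fits with a library left out, and their edgeR adjusted p was 0.659 and 0.65. RHOB had 132.7 ± 8.70 and 110.9 ± 5.32 CPM and did not pass. The 21 Rap1 partners of ARHGAP29 (12 higher, 9 lower, camera adjusted p = 0.554) and 24 YAP and TAZ targets (9 higher, 15 lower, 0.871) did not pass, and neither did 29 integrin and adhesion genes (20 higher, 9 lower, 0.0694), where CDH6 had 22.0 ± 2.07 and 34.7 ± 4.60 CPM (DESeq2 adjusted p = 0.0282, called in 1 of those 6 fits, edgeR adjusted p = 0.66) and ITGA7 84.1 ± 7.99 and 62.9 ± 2.48. Control library 2 had the lowest mean of the actin list (-0.214), and without it the list no longer passed (median 0.03, camera adjusted p = 0.222), nor without siRNA library 3 (median 0.07, 0.0781). Its median was 0.17 without control library 3, 0.18 with scaling by library size only and 0.19 on FPKM. The latter settings also raised the median of all genes from -0.02 to 0.06 and 0.07. The adhesion list passed without siRNA library 1 (0.0418), with scaling by library size only (0.0466) and on FPKM (0.0408).

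Collagen and extracellular matrix genes were lower as a group. Of 40, 32 were lower in value (median -0.20, camera adjusted p = 0.00154, and adjusted p = 0.654 with an estimated correlation). SPARC, a collagen-binding matrix protein, had 3503 ± 300.2 CPM in control and 2492 ± 262.3 after siRNA (SD, n = 3), COL1A2 52254 ± 11429 and 35378 ± 6417, COL16A1 780.2 ± 91.9 and 612.0 ± 34.8, and the crosslinking enzyme gene LOX 117.0 ± 11.7 and 93.3 ± 8.52. No member passed over all genes or adjusted over the list alone. Per-library means of the matrix list overlapped, at 0.0266 in siRNA library 1 against -0.0147 in control library 2. The 17 tested osteogenic genes (3 higher, 14 lower, camera adjusted p = 0.0613) did not pass as a list, although SPARC passed as lower when adjusted over that list alone. Of these 17 genes 9 are also in other lists. SPARC, COL1A1 and COL1A2 are shared with the matrix list, so the 2 lists are not separate results. The 20 chondrogenic genes (7 higher, 13 lower, 0.271) and 26 matrix proteases and inhibitors (10 higher, 16 lower, 0.631) did not pass, with MMP1 at 62.5 ± 8.04 and 89.3 ± 9.11 CPM and TIMP3 at 312.4 ± 43.5 and 242.8 ± 5.84. The matrix call ended without control library 1 (median -0.11, camera adjusted p = 0.229), which had the highest list mean (0.129, and 0.558 for endothelial markers), or without siRNA library 2 (-0.10, 0.0876), and the osteogenic list passed in 6 alternatives. The matrix median was -0.12 with scaling by library size only and -0.11 on FPKM, with the call kept. In these settings the median of all genes rose from -0.02 to 0.06 and 0.07. The osteogenic alternatives were leaving out control library 3 (0.00555) or siRNA library 1 (0.00796), scaling by library size only (0.0330), the stricter CPM filter (0.0330), FPKM (0.0113) and the replicate block (0.0202).

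Stress, interferon and p53 target genes were lower as groups. Of 32 genes of the unfolded protein and integrated stress response 27 were lower in value (median -0.20, camera adjusted p = 0.000649, and adjusted p = 0.547 with an estimated correlation), including DDIT4 (99.8 ± 33.1 against 53.6 ± 13.7 CPM), SLC3A2, CHAC1 and VLDLR. Of 32 type I interferon response genes 23 were lower (median -0.24, camera adjusted p = 0.00154, and adjusted p = 0.547 with an estimated correlation). Among these HERC6 passed when adjusted over the list alone, at 1.77 ± 0.493 and 0.362 ± 0.116 CPM (edgeR adjusted p = 0.606, DESeq2 adjusted p = 0.0089, called in 1 of 6 fits with a library left out), while the RNA sensor gene IFIH1 had 2.51 ± 0.467 and 1.04 ± 0.524 and PARP14 37.1 ± 2.78 and 28.3 ± 1.53. Of 29 p53 targets 20 were lower (median -0.11, camera adjusted p = 0.0489, and adjusted p = 0.547 with an estimated correlation). MDM2 passed adjusted over that list alone, and CDKN1A, the p21 inhibitor of cyclin-dependent kinases, had 696.7 ± 102.0 and 492.8 ± 54.4 CPM, FDXR 126.7 ± 10.3 and 94.7 ± 6.99, and GADD45A 104.1 ± 11.8 and 77.1 ± 5.04. Apoptosis regulators (11 of 27 higher, camera adjusted p = 0.871), with BCL2 at 5.41 ± 0.369 and 8.13 ± 0.240 CPM, heat shock genes (10 of 20 higher, 0.871) and NF-kB and cytokine genes (11 of 26 higher, 0.871) did not pass. Per-library means of the p53 list overlapped, at -0.0127 in siRNA library 1 against -0.0290 in control library 3. Those of the stress and interferon lists did not overlap. Control library 1 had the highest mean of the interferon (0.377) and stress (0.256) lists, and also of the endothelial markers (0.558), whose median was -0.26. Without control library 1 the interferon call ended (median -0.16, camera adjusted p = 0.168), as it did on the deposited FPKM (median -0.02, 0.133), and with scaling by library size only the median was -0.15 with the call kept. The p53 median was -0.06 without control library 1, -0.03 with scaling by library size only and -0.18 without control library 3. The stress median was -0.12 without control library 1 or with scaling by library size only and -0.10 on FPKM, with the call kept. The median of all genes itself rose from -0.02 to 0.06 with library size only and to 0.07 on FPKM. The FPKM setting also kept only genes with FPKM of 1 or more in 3 libraries. Its log2(FPKM + 1) scale compresses changes of low genes, so low members count less or not at all there. The p53 call ended without control library 1 or 2 or siRNA library 2 or 3 (camera adjusted p = 0.342, 0.129, 0.140 and 0.226, medians -0.06, -0.09, -0.07 and -0.10). It also ended with scaling by library size only (0.0665) or by DESeq2 size factors (0.0500019, median -0.11).

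**Figure D3:**
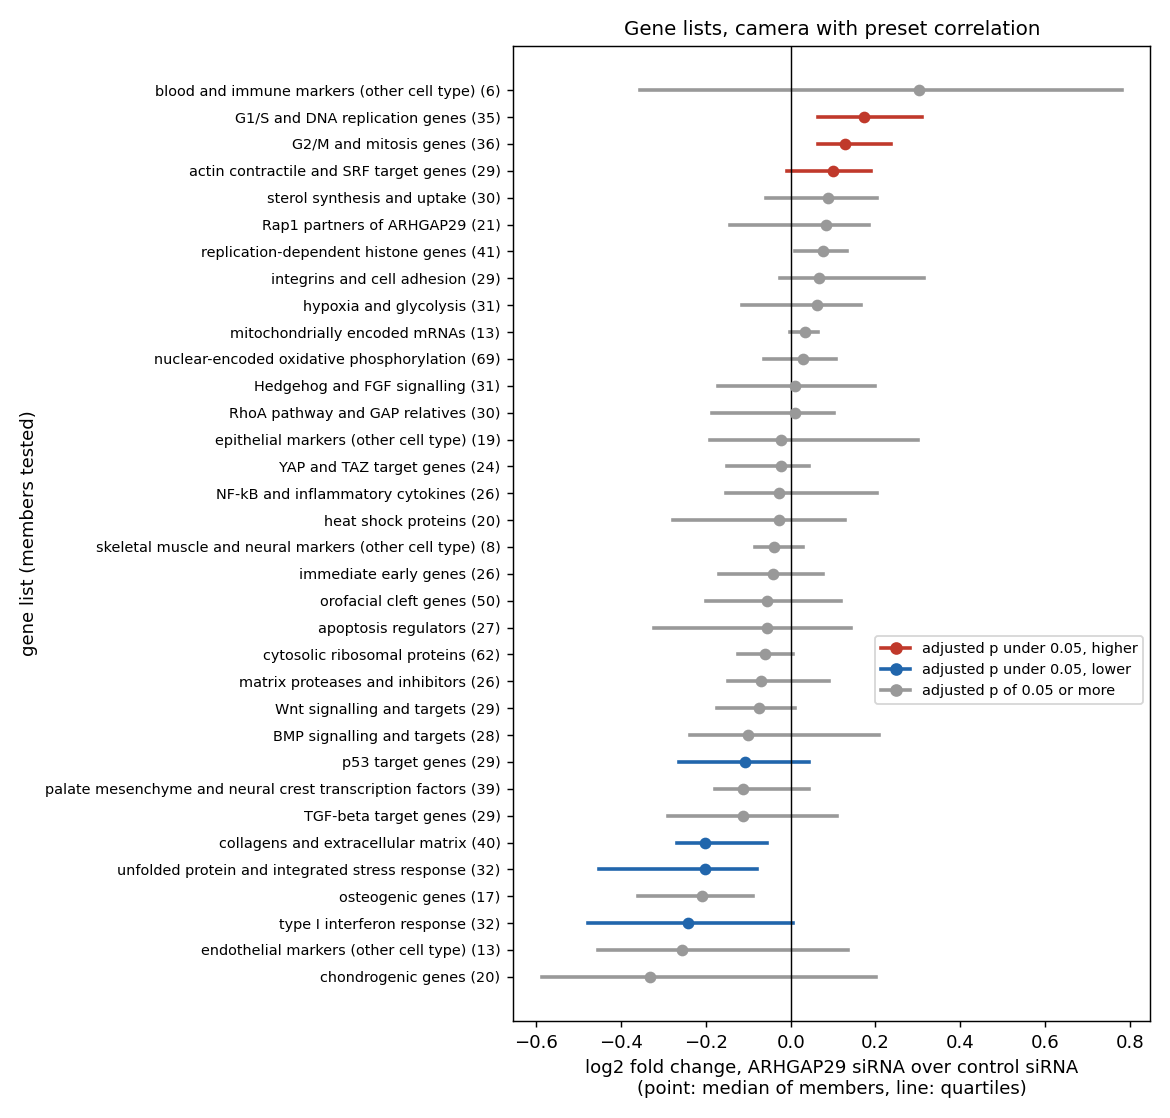
Median log2 fold change (point) and quartiles (line) of the tested members of each of 34 gene lists, ARHGAP29 siRNA over control siRNA, on the horizontal axis, coloured by camera with the preset correlation. The 3 lists past as higher have medians of 0.17, 0.13 and 0.10, and the 4 past as lower have medians from -0.24 to -0.11.

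Genes tied to palate development showed no group shift past the test. Of 50 tested orofacial cleft genes 22 were higher and 28 lower in value (camera adjusted p = 0.871), and of 39 transcription factors of palate mesenchyme and neural crest 14 were higher and 25 lower (0.354). TBX2 had 293.0 ± 40.5 CPM in control and 357.2 ± 27.4 after siRNA, SOX9 23.3 ± 5.84 and 30.5 ± 0.466, SNAI2 11.7 ± 2.29 and 8.96 ± 0.339, and ALX4 39.1 ± 6.49 and 28.4 ± 4.57, with edgeR adjusted p between 0.850 and 0.912. TGF-beta targets (11 of 29 higher, camera adjusted p = 0.276, but 0.0408 as lower on FPKM), BMP genes (11 of 28 higher, 0.871), Wnt genes (8 of 29 higher, 0.416), Hedgehog and FGF genes (16 of 31 higher, 0.915) and immediate early genes (11 of 26 higher, 0.913) did not pass. MYC, a Wnt target and immediate early gene, had 24.8 ± 3.59 and 14.4 ± 4.60 CPM, SMAD3 226.4 ± 20.6 and 181.6 ± 15.8, and FGF5 140.8 ± 10.7 and 173.2 ± 15.9.

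Metabolic and translation genes did not pass as lists either. Oxidative phosphorylation genes of the nucleus (39 of 69 higher, camera adjusted p = 0.428) include NDUFB10, a complex I subunit gene, which passed as higher when adjusted over the list alone (11.8 ± 1.76 against 26.7 ± 4.27 CPM). The 13 mitochondrially encoded mRNAs (9 higher, 0.535), 31 hypoxia and glycolysis genes (18 higher, 0.535) and 30 sterol genes (19 higher, 0.282) had no member past the edgeR test, while DESeq2 called MSMO1 of the sterol list as lower (adjusted p = 0.00525, and in 2 of 6 fits with a library left out). MSMO1, a sterol demethylation enzyme gene, had 2597, 230 and 2278 counts in control and 299, 220 and 459 after siRNA, so control library 2 lay with the siRNA libraries, and without it MSMO1 passed as lower (edgeR adjusted p = 0.0177, range over alternatives 0.00525 to 1.00). Of 62 cytosolic ribosomal protein genes, which have many pseudogene copies, 44 were lower in value (camera adjusted p = 0.329), a direction whose median changed sign under scaling by library size only, while RPL29 had 27.1 ± 3.74 and 53.1 ± 13.8 CPM and was called by DESeq2 as higher (adjusted p = 0.0106, and in 5 of 6 such fits). Without control library 2 the ribosomal list passed as lower (0.000133), and without siRNA library 1 the mitochondrial mRNAs passed as higher (0.0431).

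No list of markers of other cell types passed camera. Epithelial markers (9 of 19 higher, camera adjusted p = 0.464), endothelial markers (5 of 13 higher, median -0.26, 0.464), blood and immune markers (3 of 6 higher, 0.871) and skeletal muscle and neural markers (3 of 8 higher, 0.904) had no member past the edgeR test over all genes or adjusted over the list alone. Of the 19 epithelial markers, 3 were higher and 1 was lower in every siRNA library than in every control library, namely PERP, SFN, KRT18 and OCLN in that order. SFN (0.217 ± 0.123 CPM in control and 0.792 ± 0.136 after siRNA) and OCLN (0.449 ± 0.129 and 0.112 ± 0.0999) rest on few reads. PERP, a desmosomal gene, had 31.9 ± 1.92 CPM in control and 43.3 ± 1.48 after siRNA, the keratin gene KRT18 8.47 ± 1.19 and 10.5 ± 0.829, and EGFL7 30.4 ± 3.78 and 24.8 ± 1.18. No list passed camera with an estimated correlation or fry's directional test. In fry's mixed test, which asks for change in either direction, 5 lists passed, namely integrins and adhesion (adjusted p = 0.00215), epithelial markers (0.00215), G1/S (0.0146), actin (0.0467) and p53 targets (0.0467). The median and the mean of fold changes, or the median and camera's direction, had opposite signs in the lists of Rap1 partners, RhoA pathway, orofacial cleft, epithelial, NF-kB, skeletal and neural, and immediate early genes. Under scaling by library size only, the medians of 11 lists changed sign, namely YAP and TAZ targets, matrix proteases, apoptosis, NF-kB, Wnt, immediate early, orofacial cleft, ribosomal, heat shock, epithelial, and skeletal and neural genes.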

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

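Of the settings here, edgeR without robust estimation and the repeats of DESeq2 (a library left out, block, TMM-based factors) were tests chosen after the results were seen. ARHGAP29 stayed lower in all 18 alternatives (log2 fold change -1.23 to -0.67, the latter on the compressed log2(FPKM + 1) scale), and DESeq2 alone brought it past the threshold (-1.19, adjusted p = 6.15e-11; range over alternatives 6.15e-11 to 0.577). The count of genes changed was 74 with DESeq2 (32 by at least 2-fold), 4 with limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1), 2 without the FPKM filter and 0 at an adjusted p of 0.01, with the same values for 2-fold changes outside DESeq2. Leaving out 1 library gave 0 to 5 genes, also at 2-fold (0 without siRNA library 1 or 3, 2 without siRNA library 2, 5 without control library 2, and 1 gene other than EXTL3 without control library 1 or 3), and the remaining settings gave 1. EdgeR called 1 gene with DESeq2 size factors, without a low-count filter and without robust estimation, and DESeq2 called 76 with TMM-based factors. These choices therefore do not account for the 74. Of the 12 higher and 12 lower DESeq2 genes named, COA8 alone had a larger SE in edgeR (0.503 against 0.486). For ARHGAP29 the log2 fold change was -1.20 ± 0.141 (SE) in edgeR and -1.19 ± 0.155 in DESeq2. A larger SE in edgeR is thus argued against for these genes. The quasi-likelihood F-test of edgeR gave ARHGAP29 an unadjusted p of 5.43e-05, above the adjusted p of 6.15e-11 from DESeq2's Wald test. This was so although edgeR's SE was smaller and the fold changes were nearly equal. For ARHGAP29 the gap therefore lies in how each tool turns fold change and SE into a p-value, before adjustment over genes. How the tools do this was not varied, and other differences between the tools were not tested. DESeq2 called 56 to 204 genes with 1 library left out (204 without control library 2, of which 67 were among the 74). Of the 74 calls, 21 remained in all 6 such fits. Lists past camera numbered 0 with an estimated correlation, 0 with fry's directional test, and 4 to 10 with 1 library left out (4 without siRNA library 2), and with other settings the count stayed within 6 to 10. Of the alternatives for the 7 passing lists, 64 kept the call and 27 ended it, and in 17 cases another list passed. Scaling by library size only changed the sign of 11 list medians, none among the 7, and moved the median of all genes from -0.02 to 0.06. On log2(FPKM + 1) that median was 0.07, so list medians under these settings include a shift of all genes. Deviations of same-numbered libraries correlated weakly, at 0.0870, 0.151 and 0.174, and each library correlated best with its own number. Different-numbered libraries correlated at -0.151 to 0.0214, so a weak pairing by number stays open, while the main test used group alone. With a replicate block edgeR called 1 gene, camera 9 lists (all 7 among them) and DESeq2 142 genes. Depth was 26966776 to 47150470 counts, and in the simulation edgeR found 32.8% of 2-fold changes. With 99 edgeR calls in the simulation against 1 here, the adjusted threshold was easier to reach there, so that share may be too high for these data.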

Other observations

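The tests of a single odd library and of glycosaminoglycan genes for EXTL3, of the estimated correlation for the G1/S list, and of ATF7-NPFF were chosen after the results were seen, as were the counts of members per split; the criterion of the glycosaminoglycan test was also changed after its result was seen.

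CANT1, a calcium-activated nucleotidase gene picked from DESeq2's higher calls after values were seen, was 1.72-fold higher (130.4 ± 25.9 against 223.6 ± 18.7 CPM, SD, n = 3, DESeq2 adjusted p = 0.00999, edgeR adjusted p = 0.606), and was called in 3 of 6 DESeq2 fits with 1 library left out. PCNX3, outside the fixed lists, was at 264.5 ± 10.4 and 439.3 ± 16.4 CPM. Genes that differed at least 4-fold between libraries of the same group, among 8847 with 10 CPM or more in a library, numbered 234 (2.64%). Their share was 4.04% among genes that overlap another listed gene and 2.06% among the rest (Fisher's exact test across genes, which are not independent, odds ratio 2.00, p = 4.02e-07). Control library 2 was the farthest from its group in 85 of them.

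EXTL3 was 7.43-fold higher after ARHGAP29 siRNA. Reads moved from a listed neighbour are argued against, because FZD3 and INTS9, the genes within 100 kb, changed by 0.916 CPM in sum (10.3 ± 2.92 to 11.2 ± 1.497, SD, n = 3) while EXTL3 gained 105.6. A single odd library is argued against too, since the smallest log2 fold change with 1 library left out was 2.75. A wider rise of glycosaminoglycan genes stays undecided: 41 genes of that kind, listed without EXTL3, CHST14 and CANT1 because these had been seen among DESeq2's calls, had a median of -0.0923 with 18 higher and 23 lower (upper quartile 0.148, camera direction higher, not past its threshold), which the first criterion, a median under 0.1 with an upper quartile under the change of EXTL3, would have counted against it. An effect of ARHGAP29 loss, an effect of the siRNA sequence on other transcripts, and a transcript outside the table remain open and were not tested.

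The G1/S list was higher with a median of 0.17, and 14 of its members were higher in every siRNA library. Control library 2 as the source is argued against by its list mean (-0.0355), which lay between those of the other controls (-0.174 and 0.00135), and the median without it was 0.21. The planned test of the varying share of type I collagen counts could not decide. Scaling without COL1A1 and COL1A2 gave 0.18 but moved all genes too little, by 0.00565. Such a share would scale the other genes alike, yet the G1/S quartiles (0.0654 and 0.309) lay above the median of all genes (-0.0159). These values argue against it for the list as a whole. Members that vary together between libraries may account for the camera call, since the adjusted p with an estimated correlation (0.137) was 0.547. The rise in p cannot be credited to the correlation alone, because that setting raises p by itself. For TGF-beta targets the estimate (-0.0113) was under the preset 0.01, yet camera's unadjusted p went from 0.0973 to 0.134. A change in proliferation after ARHGAP29 siRNA and a difference in culture density stay open as hypotheses, untested.

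DESeq2 called 74 genes where edgeR called 1. Overlapping genes are argued against as what lowers edgeR's prior degrees of freedom. These were 3.16 with all genes and 3.28 without overlapping ones, where edgeR called 2 genes. For the call of ATF7-NPFF, a move of reads to the overlapping NPFF may account for part of it, since NPFF gained 57.7% of the CPM that ATF7-NPFF lost, but ATF7, which also overlaps it, had 14.6 ± 3.47 and 19.1 ± 0.413 CPM (SD, n = 3) and stays open as another place of these reads. The sum of ATF7-NPFF and NPFF was 2.81 ± 0.588 CPM in control and 1.69 ± 0.578 after siRNA (exact permutation p = 0.1, the smallest possible). DESeq2's share of false calls in the simulation, 48 of 160, leaves part of the 74 open to error. That share depends on the number of genes changed in the simulation.

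With 10 splits of 3 against 3 libraries no share under 0.05 can be reached. The real split gave 1 gene changed in edgeR, also at 2-fold, and the highest other split gave 3, with 9 of 10 splits giving at least 1. For lists the real count was 7 and the highest other 9, with 3 of 10 splits at 7 or more. For DESeq2 the real count was 74 and the highest other 97, with 2 of 10 splits at 74 or more. That other split sets control libraries 1 and 3 and siRNA library 3, the 3 deepest, against the 3 shallowest. It had 1539 genes with an unadjusted edgeR p under 0.05 against 786 in the real split. The remaining splits had 208 to 839. Because this split was picked for its high count, a structure of the samples besides the siRNA groups stays open and was not tested. Control library 1 and siRNA library 1 had nearly equal totals (41504980 and 41483822), so depth as the source of such a structure was not tested.

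Members that separated the sides numbered 14 for the G1/S list in the real split and at most 6 in another, with a camera p of 1.64e-06 against a smallest of 5.46e-05 elsewhere. That list had the smallest camera p of all lists in the real split, so the comparison favours that split. Camera p over splits was taken for this list alone, and p53 targets were not counted over splits. For the other lists counted, another split matched or exceeded the real one, with 7 against 10 for collagens and matrix, 6 against 10 for the stress response, 6 against 6 for interferon, 5 against 7 for G2/M and 6 against 9 for actin. A test of whether the collagen list rests on control library 2 was set aside because the number of patterns weighed is limited. The median without that library was -0.18 against -0.20 with it, but its list mean was the lowest of the controls (-0.0147), so that library was not the source of the lower values after siRNA. The libraries whose omission ended that call were control library 1 and siRNA library 2 (camera adjusted p = 0.229 and 0.0876).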
